A study of Mus musculus with 4 samples.

How the data were processed

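Gene expression in mouse brain was measured on 4 two-colour oligonucleotide arrays, each carrying RNA of mice with permanent middle cerebral artery occlusion (PMCAO) in one dye and RNA of sham-operated mice in the other. Each time after saline injection, 6 h and 24 h, was covered by 2 arrays of opposite dye orientation. On sample 1 of each time the PMCAO RNA carried Cy5, and on sample 2 it carried Cy3. The labels number these arrays and call them dye swaps without saying whether sample 1 and sample 2 hold separate RNA, so p-values measure only the spread between these arrays, which may be technical. The labels do not say how the RNA of the 3 mice in a group was combined. All 4 arrays lay on 1 slide with 1 scan, so no slide or scan batch could be tested.

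The scanner tables deposited by the authors hold spot intensity values (mean signal, local background median and processed signal of each channel) and a log10 ratio of Cy5 over Cy3, made with Agilent Feature Extraction 9.5.3.1, per the file headers. The processed signals were background-subtracted and dye-normalised by that software, per the file headers. The deposited series table gives 1 further value per probe and array. Its size equalled the linear ratio of processed Cy5 over Cy3 signal for 100.0% of probes to within rounding at 2 decimals. Its sign was negative throughout on sample 1 and positive throughout on sample 2 of each time, with column medians of -0.96 and 0.96 at 6 h and -0.91 and 0.95 at 24 h. What the sign stands for, and whether the authors centred the values further, stayed unknown. Probe coordinates are those of mouse build mm7, per the file headers.

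Mean signals were corrected with normexp (offset 50) and normalised within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Outlier-flagged spots (112 to 142 per array) were removed and saturated spots (0 to 2 per array) kept. Log2 ratios were turned to PMCAO over sham on every array, spots of a probe were averaged, and the brightest probe by mean intensity over the 4 arrays stood for its gene. A gene was tested when its probe was well above background on both arrays of at least 1 of the 4 RNA groups, which left 19125 genes of 27670 names. Of 41174 probes, 22944 were named through their accession in a RefSeq table of assembly GRCm38.p6, 6664 through their symbol and 3108 through an older symbol, while 8458 kept the name in the files. That table supplied names only. The precision of every value is limited by the number of arrays.

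A linear model of all 4 arrays gave 1 coefficient per time and the 24 h minus 6 h difference, without a dye term because orientation was balanced within each time. A dye effect then cancels in the mean of a time but stays in the spread. It does not cancel where an array is left out, as 1 orientation then remains at that time. Both times shared 1 estimate of the spread (2 residual and 3.53 prior degrees of freedom). Moderated tests in limma were adjusted by the Benjamini-Hochberg method at 0.05, and errors are standard errors of the model with n = 2 arrays per time. Sham at 24 h was set against sham at 6 h by a separate-channel model after Aquantile normalisation between arrays, with an intraspot correlation of -0.411. With an array left out, that correlation was held at this value, because it could not be estimated from 3 arrays.

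A group that was not well above background on both its arrays has only a bound. The fold is then given as at least N-fold, from the bright group's mean against the lowest detected signal or the dim probe's own, whichever was higher, after loess and Aquantile. The 30 gene lists were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over the 30 lists within each comparison. Counts of list members past the test are given over all genes and adjusted over the list alone. Across genes, random relabelling used 100000 resamples in scipy 1.17.1 under Python 3.11.15, and plots used matplotlib 3.10.9.

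Before the data were examined, the lists, tests and alternatives were fixed, with this rule for named genes. For each time and for the difference, the 10 highest and 6 lowest log2 ratios past the test were taken, with both arrays of that time in the same direction, leaving out names that are only clone or predicted-gene identifiers. The 2 members of each list with the smallest p at each time, and the 5 largest changes each way in sham, were added. This gave 122 genes, of which 3 are not reported here. Other list members are named beside their list's count, and were chosen after their values were seen.

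The fits were tested on simulated arrays of 19117 genes with 200 changed genes, 50 per fold size. For the ratios, each gene's dye effect and noise came from the fit with the sample number as a block. That noise was the same at both times, while in the data the arrays of 6 h differed less than those of 24 h. The shares below therefore do not compare power between the times. At 6 h, 8% of genes changed 1.5-fold were recovered, 82% of those changed 2-fold and 96% of those changed 4-fold, with 0 unchanged genes called. At 24 h these shares were 6%, 84% and 100%, again with 0 unchanged genes called. For the difference they were 0%, 4% and 90%, with 0 unchanged genes called, and for sham 36%, 94% and 100%, with 4 unchanged genes called. The sham channels were simulated with noise of a set size, largely shared within a spot, and no dye effect. The data differed, with an intraspot correlation of -0.411, so the sham shares do not measure the power of that test. The alternatives were the processed signals, the deposited series values, no background subtraction, median centring, no filter or a stricter filter on dim probes, the sample number as a replicate block, trended robust variances, all probes, each time alone, a 1.5-fold rule, quantile normalisation of channels for sham, an estimated correlation for lists, and leaving out each array.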

Results

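Brain RNA of male C57BL/6J mice was profiled after permanent middle cerebral artery occlusion, a model of ischemic stroke in which a nylon filament blocks the artery, and after a sham operation in which the neck vessels were exposed and the wound closed. Both arms received saline into the cerebral ventricle, and brains were taken 6 h or 24 h later from groups of 3 mice. The design text names the hemisphere opposite the occlusion as the tissue put on the arrays, the sample labels say only brain, and the arrays carry no measurement that settles it. Each time had 2 arrays of opposite dye orientation. Between 66.3% and 73.7% of spots were well above background in the PMCAO channel and between 67.3% and 73.6% in the sham channel. Across genes, which are not independent replicates, the log2 ratios of the 2 arrays correlated at 0.582 at 6 h and 0.671 at 24 h. Between the times, arrays of the same dye orientation correlated at 0.612 and 0.628 and arrays of opposite orientation at 0.319 and 0.382. The comparisons ask which transcripts differed after ischemia at each time, whether the response differed between the times, and whether sham itself moved.

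At 6 h after injection, the genes with the largest increases in the occluded mice included transcripts of stress and inflammation. The largest log2 ratio belonged to Hspa1a, an inducible heat shock protein, at 3.85 ± 0.15 (model SE, n = 2 arrays), or 14.4-fold. Its near-identical copy Hspa1b may share the probe's signal, so the gene is uncertain, and its 4 probes spanned 2.03 to 3.85. It was followed by Atf3, a stress-induced transcription factor, at 2.66 ± 0.13, S100a9, a calcium-binding protein abundant in neutrophils, at 2.61 ± 0.10, and Npas4, an activity-dependent transcription factor of neurons, at 2.60 ± 0.20. The lower genes were led by the organic anion transporter Slco1a4 at -1.03 ± 0.10 and the amino acid transporter Slc38a5 at -1.02 ± 0.10. Of 19125 genes tested, 156 were higher and 7 lower at an adjusted p under 0.05, and 85 of the higher and 2 of the lower genes changed at least 2-fold.

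The other leading higher genes were Cd14, a co-receptor for lipopolysaccharide, at 2.55 ± 0.14, the chemokines Ccl4 at 2.50 ± 0.25 and Ccl2 at 2.49 ± 0.15, the transcription factor Maff at 2.32 ± 0.11, and Tmem252 at 2.12 ± 0.10. The beta tubulin Tubb6 stood at 2.35 ± 0.10 on its brighter probe, while its other probe gave 0.05 at 6 h and -0.07 at 24 h. Besides the transporters, the lower genes were Erbb3, a neuregulin receptor, at -0.91 ± 0.08, Trim59 at -0.71 ± 0.09, Wnt9a, a secreted signalling protein, at -0.69 ± 0.09, Gpr17, a receptor of oligodendrocyte precursors, at -0.68 ± 0.09, and the expressed sequence AI593442 at -0.62, which was named after its value was seen. Adjusted p-values of these named genes ran from 0.00386 for Hspa1a to 0.0486 for AI593442, and both arrays moved the same way for each. Trim59 passed on 1 of its 2 probes, with the other at -0.28. The probe of S100a9 lies on chromosome 3 at 90822865 to 90822924 in mm7 coordinates, and that of Hspa1a on chromosome 17 at 33066911 to 33066970.

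Immediate early and early response genes, which are transcribed within minutes to hours of a stimulus, rose as a group at 6 h: 14 of 30 tested members were higher and 0 lower (26 higher and 1 lower adjusted over the list alone), with a median log2 ratio of 0.61. The members that rose were Atf3, Bdnf, Ccn1, Egr4, Fos, Fosb, Fosl2, Gadd45b, Jun, Junb, Klf4, Maff, Npas4 and Ptgs2. In camera the adjusted p was 1.39e-34 (adjusted p = 0.21 with an estimated correlation). Of the 30 lists, camera called 18 at 6 h, 18 at 24 h and 16 for the difference, and fry called 14, 20 and 13 as moving one way. Both called 13, 16 and 12 of them. With an estimated correlation camera in limma called 0 in each comparison (7, 6 and 6 at an unadjusted p under 0.05), so list calls below rest on the preset correlation. Glucocorticoid response genes had 5 of 14 higher and 0 lower (10 and 0 adjusted over the list alone), namely Angptl4, Cdkn1a, Errfi1, Nfkbia and Pdk4, with a median of 0.70 and an adjusted p = 1.24e-16 (adjusted p = 0.21 with an estimated correlation). Cdkn1a, a cell cycle inhibitor, stood at 1.87 ± 0.08 and Errfi1, an inhibitor of growth factor receptors, at 1.25 ± 0.11. Among p53 and apoptosis genes, 5 of 19 were higher and 0 lower (9 and 0 adjusted over the list alone): Casp4, Cdkn1a, Gadd45g, Pmaip1 and Trp53inp1. That list's median was 0.12, with an adjusted p = 1.59e-09 (adjusted p = 0.21 with an estimated correlation), and Pmaip1, a pro-apoptotic protein, stood at 1.41 ± 0.09. Heat shock proteins and chaperones had 3 of 19 higher and 0 lower (4 and 0 adjusted over the list alone), which were Hspa1a, Hspb1 at 1.24 ± 0.08 and Dnajb1, with a median of 0.10 and an adjusted p = 0.000154 (adjusted p = 0.221 with an estimated correlation).

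Inflammatory and tissue-response lists also had higher members at 6 h. Of 21 chemokines, 6 rose and 0 fell (11 higher and 1 lower adjusted over the list alone): Ccl2, Ccl3 at 1.96 ± 0.14, Ccl4, Ccl9, Ccl17 and Cxcl1 at 1.57 ± 0.17. Their median was 0.48, with an adjusted p = 9.75e-12 (adjusted p = 0.211 with an estimated correlation). Reactive astrocyte markers had 7 of 21 higher and 0 lower (14 and 0 adjusted over the list alone), namely Aspg, Cd14, Emp1, Lcn2, Osmr, Sphk1 and Timp1, a median of 0.53 and an adjusted p = 4.83e-24 (adjusted p = 0.211 with an estimated correlation). Matrix proteases, inhibitors and matrix genes had 8 of 25 higher and 0 lower (10 and 0 adjusted over the list alone), among them Adamts1 at 1.64 ± 0.09, Col4a1, Col4a2, Plaur and Timp1 at 1.71 ± 0.09. The median was 0.16, with an adjusted p = 2.3e-11 (adjusted p = 0.21 with an estimated correlation). Neutrophil and monocyte markers had 3 of 20 higher and 0 lower (6 and 0 adjusted over the list alone), S100a8 at 1.92 ± 0.10, S100a9 and Retnlg, with a median of 0.18 and an adjusted p = 6.6e-10 (adjusted p = 0.221 with an estimated correlation). Single members rose among cytokines (Inhba at 0.86 ± 0.09, 1 of 15), oxidative stress genes and metallothioneins (Hmox1 at 1.21 ± 0.08, 1 of 18), complement and acute phase genes (Hp at 1.08 ± 0.12, 1 of 13) and endothelial adhesion genes (Icam1 at 0.85 ± 0.09, 1 of 7), with 0 lower in each. Icam1 and Adamts1 each passed on 1 of 2 probes, with the others at 0.25 and 0.65, and Timp1 on 2 of 3. For the single-member lists, adjusted over the list alone these counts were 4, 3, 1 and 1 higher, and 1 adhesion gene lower. Hypoxia and glycolysis genes had a median of 0.17 over 25 genes, with 4 higher adjusted over the list alone. Camera's adjusted p was 1.19e-05 for cytokines, 1.06e-06 for hypoxia genes, 0.00531 for oxidative stress genes and 0.00166 for complement genes (adjusted p = 0.221, 0.211, 0.283 and 0.214 with an estimated correlation), and 0.339 for adhesion genes.

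Other lists that camera called at 6 h had at most 1 member past the test over all genes. Cholesterol synthesis genes had 0 of 17 past the limma test, 7 higher adjusted over the list alone and 7 higher at an unadjusted p under 0.05. Their median was 0.29, with 15 members above 0 and an adjusted p = 4.46e-08 (adjusted p = 0.211 with an estimated correlation). Striatal neuron markers, genes of the medium spiny neurons, had 0 of 14 past the limma test, 3 lower adjusted over the list alone and 4 lower at an unadjusted p under 0.05. Their median was -0.19, with an adjusted p = 0.000216 (adjusted p = 0.211 with an estimated correlation). Adora2a, an adenosine receptor of these neurons, was at -0.77 ± 0.16 with an adjusted p = 0.15, and its second probe gave -0.01. Endothelial markers had 1 of 15 lower, Slco1a4, and 0 higher (5 lower and 1 higher adjusted over the list alone). Its median was -0.16, with an adjusted p = 0.00236 (adjusted p = 0.221 with an estimated correlation). Endoplasmic reticulum stress genes had 0 of 19 past the limma test, 2 higher adjusted over the list alone and 6 higher at an unadjusted p under 0.05. The median was 0.14, with an adjusted p = 2.03e-05 (adjusted p = 0.221 with an estimated correlation). Both tested red blood cell markers lay above 0, Hba-a1 at 0.49 ± 0.08 and Alas2 at 0.39 ± 0.09. Neither passed over all genes, both passed adjusted over the list alone, and the list's adjusted p was 0.000716 (adjusted p = 0.221 with an estimated correlation). Choroid plexus and ependyma markers had a median of -0.09, 0 of 13 past the limma test on either count (1 lower at an unadjusted p under 0.05) and an adjusted p = 0.0438 (adjusted p = 0.62 with an estimated correlation).

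In 11 further lists no member passed over all genes in limma at 6 h, and camera called none of them, with adjusted p-values from 0.0627 for astrocyte markers to 0.987 for pericyte markers. Interferon response genes had a median of 0.03 over 29 genes, with 2 higher adjusted over the list alone (3 higher and 1 lower at an unadjusted p under 0.05). Microglia and macrophage markers had a median of 0.10 over 22 genes, with 1 higher and 2 lower adjusted over the list alone (3 and 3 unadjusted). For the other 9 the count adjusted over the list alone was 0 as well. Their medians were 0.02 for cell cycle genes (16 tested), 0.07 for circadian clock genes (16), -0.04 for astrocyte markers (14), -0.03 for lymphocyte markers (7) and 0.003 for neuron markers (22). They were 0.05 for interneuron markers (11), -0.02 for oligodendrocyte markers (17), 0.04 for pericyte, smooth muscle and meningeal markers (14) and 0.02 for pituitary markers (6). Unadjusted p-values under 0.05 were found for 2 clock genes higher and 1 lower, 1 oligodendrocyte marker higher and 3 lower, and 1 pericyte marker higher and 2 lower, and for 0 members of the remaining 6. Camera's direction was down for neuron and pituitary markers, against positive medians. The 6 h counts depended on which arrays entered the shared spread: they were 103 higher without 6 h sample 1, 76 higher without 6 h sample 2, and 940 higher without either 24 h array. The lower count was 355 or 354 without 24 h sample 1 or 2, and 0 in limma without 6 h sample 2 (34 at an unadjusted p under 0.05). With 1 of the 6 h arrays left out, 1 dye orientation remained at 6 h, so a dye effect did not cancel in those counts. The sample number, which is also the dye orientation, as a replicate block gave 1131 higher and 571 lower genes. Fitted alone, the 6 h arrays gave 942 higher and 356 lower genes, and median centring in place of loess gave 0 of either in limma (62 higher and 1 lower at an unadjusted p under 0.05).

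At 24 h the largest ratios belonged to genes of myeloid cells and inflammation. S100a9 and S100a8, the subunits of calprotectin, were 57.1-fold and 38.7-fold higher (log2 ratios 5.84 ± 0.10 and 5.27 ± 0.10). Mmp3, a matrix metalloproteinase, was at 4.58 ± 0.13, and in sham it was well above background on 1 of the 2 arrays of that time. Chil3, a chitinase-like protein of activated macrophages, was at 4.37 ± 0.13, Retnlg, a resistin-like protein of neutrophils, at 4.35 ± 0.20, and the chemokines Ccl4, Cxcl1, Ccl2 and Ccl3 at 4.46 ± 0.25, 4.26 ± 0.17, 4.18 ± 0.15 and 3.86 ± 0.14. Lower genes reached smaller sizes, led by Slc38a5 at -1.89 ± 0.10 and P2ry12, a purinergic receptor of resting microglia, at -1.72 ± 0.17. In all, 1499 genes were higher and 864 lower, of which 390 and 25 changed at least 2-fold.

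Cd14 reached 3.88 ± 0.14 at 24 h. Further leading lower genes were Rxrg, a retinoid receptor, at -1.55 ± 0.11, Gpr34, a microglial receptor, at -1.37 ± 0.13, and Slc2a5, a fructose transporter, at -1.30 ± 0.10. Adjusted p-values of the leading genes lay between 8.7e-05 for S100a9 and 0.00376 for P2ry12, and each moved the same way on both arrays. Cxcl1 was well above background on 1 of the 2 sham arrays of that time. The probe of Mmp3 lies on chromosome 9 at 7453874 to 7453933 in mm7 coordinates, and that of Slc38a5 on chromosome X at 6713250 to 6713309.

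**Figure D1:**
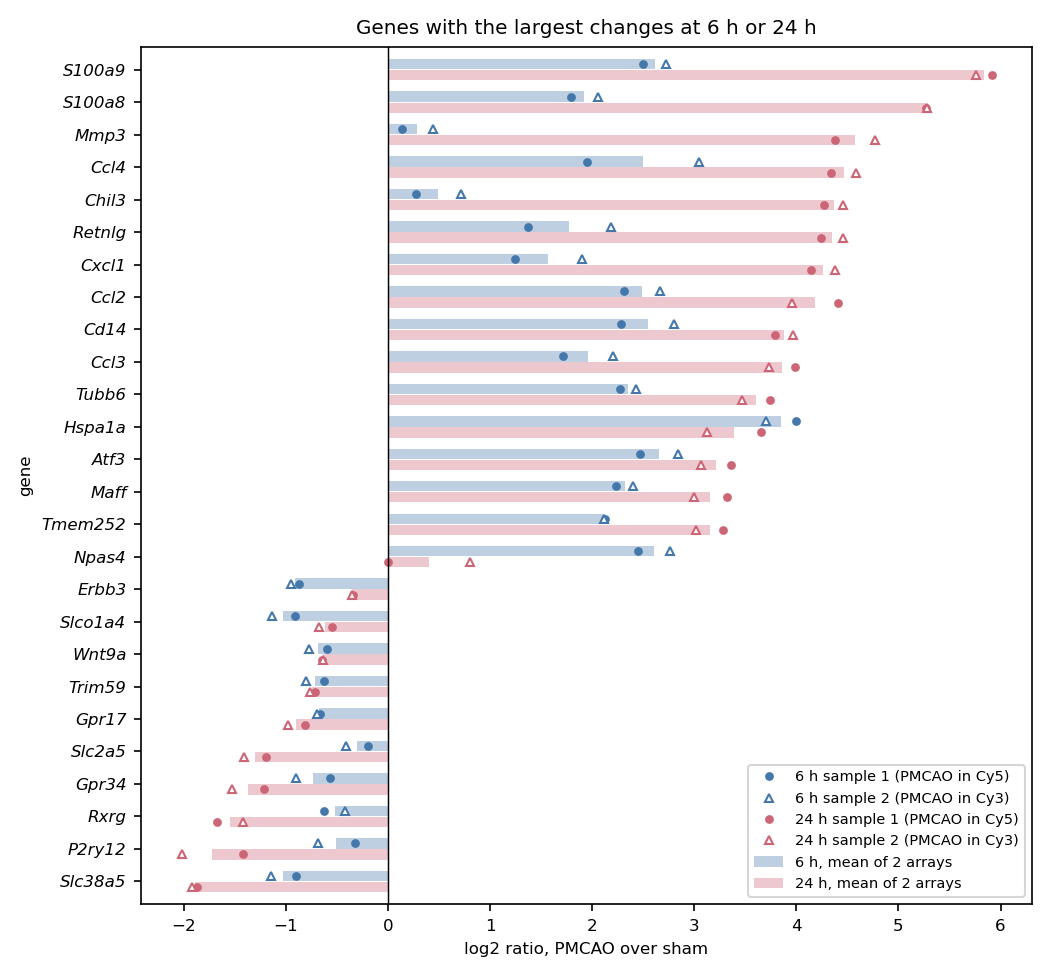
Log2 ratios of PMCAO over sham for the genes with the largest changes at 6 h or 24 h, with the gene on the vertical axis, bars for the mean of 2 arrays, filled circles for sample 1 and open triangles for sample 2, which has the opposite dye orientation. S100a9 reached 2.61 at 6 h and 5.84 at 24 h, while Npas4 stood at 2.60 and 0.40.

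Reactive astrocyte markers rose in full at 24 h: 21 of 21 were higher (21 adjusted over the list alone), with a median log2 ratio of 1.80 and an adjusted p = 2.48e-23 (adjusted p = 0.154 with an estimated correlation). Among them were Timp1, a metalloproteinase inhibitor, at 3.62 ± 0.09 (its 3 probes spanned 2.49 to 3.62), Lcn2, a siderophore-binding protein, at 2.96 ± 0.10, and Gfap, the astrocyte intermediate filament, at 1.25. By contrast, 3 of 14 general astrocyte markers were higher and 0 lower (3 and 0 adjusted over the list alone): Aldh1l1 at 0.54 ± 0.09, Gjb6 at 0.41 ± 0.08 and Sox9. Their median was 0.09, and camera's adjusted p was 0.458. Which cells carried the rise of the reactive list was not tested. Neutrophil and monocyte markers had 17 of 20 higher and 0 lower (18 and 0 adjusted over the list alone). The median stood at 1.43, with an adjusted p = 6.45e-19 (adjusted p = 0.154 with an estimated correlation). The 3 that did not pass were Csf3r, Ltf and Mpo. Red blood cell markers moved beside these groups, with Hba-a1 at 0.52 ± 0.08 (adjusted p = 0.0186) and Alas2 at 0.38 ± 0.09 (adjusted p = 0.0532), 1 of 2 higher (2 adjusted over the list alone) and an adjusted p = 0.0381 (adjusted p = 0.355 with an estimated correlation). Lymphocyte markers had 0 of 7 past the limma test on either count (1 lower at an unadjusted p under 0.05) and a median of -0.07 (adjusted p = 0.458).

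Secreted signals rose as groups at 24 h. Of 21 chemokines 16 were higher and 2 lower (16 and 2 adjusted over the list alone). Its median log2 ratio was 2.13, with an adjusted p = 2.82e-11 (adjusted p = 0.154 with an estimated correlation). Cxcl3 was at least 6.21-fold higher, since sham was not well above background, and the lower pair was Cx3cl1, a neuronal chemokine, at -0.87, and Cxcl12, made by vessels and meninges, at -1.21. Cytokines had 10 of 15 higher and 0 lower (11 and 0 adjusted over the list alone). The median over the list was 0.76, with an adjusted p = 3.63e-09 (adjusted p = 0.154 with an estimated correlation). Il11, a cytokine of the interleukin 6 family, stood at 3.58 ± 0.09 and Il1b, a pro-inflammatory cytokine, at 2.88 ± 0.09. Interferon response genes had 18 of 29 higher and 0 lower (23 and 0 adjusted over the list alone). Its median was 0.55, with an adjusted p = 8.34e-13 (adjusted p = 0.154 with an estimated correlation). Rsad2, an antiviral protein, stood at 1.39 ± 0.08 (its 3 probes spanned 0.69 to 1.39) and Ifitm3, an interferon-induced membrane protein, at 1.20 ± 0.09. Complement and acute phase genes had 10 of 13 higher and 0 lower (12 and 0 adjusted over the list alone). The median stood at 0.78, with an adjusted p = 2.27e-09 (adjusted p = 0.154 with an estimated correlation). Saa3, an acute phase apolipoprotein, stood at 3.26 ± 0.11, Hp, which binds haemoglobin, at 2.80 ± 0.12 and Cp, a copper-carrying ferroxidase, at 1.29 ± 0.08. Endothelial adhesion genes had 4 of 7 higher, among them Icam1 at 2.20 ± 0.09 and Selp, and Selplg lower (4 and 1 adjusted over the list alone). Its median log2 ratio was 0.89, with an adjusted p = 0.0287 (adjusted p = 0.279 with an estimated correlation).

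Matrix proteases, inhibitors and matrix genes had 19 of 25 higher and 0 lower at 24 h (20 and 0 adjusted over the list alone). The list's median was 0.94, with an adjusted p = 1.26e-17 (adjusted p = 0.154 with an estimated correlation). Glucocorticoid response genes had 11 of 14 higher and 0 lower (12 and 0 adjusted over the list alone). Its median was 1.34, with an adjusted p = 8.34e-13 (adjusted p = 0.154 with an estimated correlation), led by Angptl4 and Mt2. Plin4, a lipid droplet protein, stood at 2.70 ± 0.09. In the same list Sgk1, a glucocorticoid-induced kinase, stood at 1.65 ± 0.08. Sham itself was lower at 24 h than at 6 h for 6 of these 14 genes, with a median sham change of -0.51. The p53 and apoptosis genes had 13 of 19 higher and 0 lower (14 and 0 adjusted over the list alone). The median stood at 0.66, with an adjusted p = 6.13e-10 (adjusted p = 0.154 with an estimated correlation), among them Cdkn1a at 2.51 ± 0.08 and Casp4, an inflammatory caspase, at 1.65 ± 0.09. Oxidative stress genes and metallothioneins had 9 of 18 higher and 0 lower (13 and 0 adjusted over the list alone). Its median log2 ratio was 0.38, with an adjusted p = 3.6e-09 (adjusted p = 0.154 with an estimated correlation). Hmox1, haem oxygenase, stood at 2.86 ± 0.08, and Osgin1, an oxidative stress-induced growth inhibitor, at 1.63 ± 0.09, with its 3 probes between 0.12 and 1.63. Hypoxia and glycolysis genes had 8 of 25 higher and 0 lower (10 and 0 adjusted over the list alone). The median over the list was 0.34, with an adjusted p = 6.62e-06 (adjusted p = 0.154 with an estimated correlation). Among the 8 were Bnip3, Ddit4, Hk2 and Tfrc. Adm, a vasodilator peptide, stood at 2.49 ± 0.16, while the glycolytic enzymes Pgk1 at 0.24 and Aldoa at 0.06 did not pass.

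Cholesterol synthesis genes had 9 of 17 higher and 0 lower at 24 h (12 and 1 adjusted over the list alone). Its median was 0.45, with an adjusted p = 4.5e-05 (adjusted p = 0.185 with an estimated correlation), with Lss at 0.67 ± 0.08 and Insig1 at 0.65 ± 0.08. Endoplasmic reticulum stress genes had 6 of 19 higher and 0 lower (7 and 2 adjusted over the list alone). The median stood at 0.07, with an adjusted p = 0.0435 (adjusted p = 0.456 with an estimated correlation, 0.0682 in fry). The 6 were Atf5, Ddit3, Ero1a, Ppp1r15a, Sesn2 and Trib3, while the chaperones Hspa5 at -0.01 and Calr at -0.17 did not pass. Sesn2 passed on 1 of its 2 probes, with the other at 0.29. Immediate early and early response genes split, with 16 of 30 higher and 9 lower (17 and 9 adjusted over the list alone). Its median log2 ratio was 0.55, with an adjusted p = 0.00112 (adjusted p = 0.311 with an estimated correlation). The 9 lower members were Arc, Bdnf, Dusp6, Egr1, Egr2, Egr3, Egr4, Homer1 and Nr4a2, genes known to respond to neuronal activity or growth factors. Atf3 at 3.21 ± 0.13 and Maff at 3.16 ± 0.11 led the higher members. Heat shock proteins and chaperones had 4 of 19 higher, Hspa1a at 3.39 ± 0.15, Hspb1 at 2.24 ± 0.08, Bag3 and Hspb8, and 2 lower, Hspa4 and Chordc1 (4 and 3 adjusted over the list alone). The list's median was 0.05, with an adjusted p = 0.632. Cell cycle genes had 1 of 16 higher, Bub1b at 0.56 ± 0.09, and 0 lower (1 and 0 adjusted over the list alone). Its median was 0.13, with an adjusted p = 0.11. Circadian clock genes had 1 of 16 higher, Nr1d1 at 0.42 ± 0.09, and 1 lower, Per2 at -0.79 ± 0.15 (2 and 2 adjusted over the list alone), with a median of -0.04, a mean of 0.003 and an adjusted p = 0.8. For Per2 and Nr1d1, 1 of 2 and 1 of 3 probes passed.

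Striatal neuron markers fell as a group at 24 h: 9 of 14 were lower and 0 higher (9 and 0 adjusted over the list alone). The median stood at -0.59, with an adjusted p = 6.62e-06 (adjusted p = 0.154 with an estimated correlation). Among the 9 were Adora2a, Drd1 at -0.62 ± 0.08, Drd2, Pde10a, Penk and Tac1. Adora2a passed on 1 of its 2 probes, which stood at -1.06 and -0.10. General neuron markers had 2 of 22 lower, the glutamate receptor subunits Gria2 at -0.50 ± 0.08 and Grin2a at -0.59 ± 0.11, and 0 higher (2 and 0 adjusted over the list alone). Its median log2 ratio was -0.18, with an adjusted p = 0.0206 (adjusted p = 0.311 with an estimated correlation). Fry did not call the general neuron list (fry adjusted p = 0.218). Gria2 passed on 1 of its 3 probes, which spanned -0.62 to -0.21. Interneuron markers had 1 of 11 lower, Vip at -0.56 ± 0.11, and 0 higher (2 lower adjusted over the list alone), with a median of 0.04, a mean of -0.06 and an adjusted p = 0.632. Oligodendrocyte markers had 2 of 17 lower, Ugt8a, a galactolipid-synthesis enzyme, at -1.22 ± 0.08 and Aspa at -0.61 ± 0.10, and 0 higher (2 lower adjusted over the list alone). The median over the list was -0.11, with an adjusted p = 0.105.

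Microglia and macrophage markers divided at 24 h, with 7 of 22 higher and 4 lower (7 and 6 adjusted over the list alone). Its median was 0.14, with an adjusted p = 0.516. The higher members were Cd53, Cd68, a lysosomal protein of phagocytes, at 1.11 ± 0.09, Fcer1g, Fcgr1, Fcgr3, Ptprc and Tyrobp. The lower members, P2ry12, Gpr34, Siglech at -1.01 ± 0.09 and Tmem119, are known as markers of resting microglia. Endothelial markers had 5 of 15 higher and 2 lower (6 and 3 adjusted over the list alone). The median stood at 0.14, with an adjusted p = 0.458. Cdh5, the endothelial cadherin, stood at 1.45 ± 0.14 and Pecam1 at 0.93 ± 0.09, with Esam, Ly6c1 and Vwf also higher, while the transporters Slco1a4 at -0.62 ± 0.10 and Slco1c1 fell. Pericyte, smooth muscle and meningeal markers had 2 of 14 higher, Dcn at 1.13 ± 0.08 and Kcnj8 at 0.96 ± 0.09, and 1 lower, Ogn (3 and 3 adjusted over the list alone). Its median log2 ratio was 0.26, with an adjusted p = 0.24. Unlike camera, fry called the pericyte, endothelial, oligodendrocyte and heat shock lists at 24 h (fry adjusted p = 0.00313, 0.0315, 0.0132 and 0.017). Choroid plexus and ependyma markers had 1 of 13 lower, Sostdc1 at -1.01 ± 0.18, and 0 higher (1 lower adjusted over the list alone). The list's median was -0.02, with an adjusted p = 0.951. Pituitary markers had 1 of 6 higher, Prl at 1.04 ± 0.08, and 0 lower (2 higher adjusted over the list alone). Its median was 0.13, with an adjusted p = 0.199. Leaving out 24 h sample 1 gave 2920 higher and 2841 lower genes at 24 h, leaving out 24 h sample 2 gave 2491 and 1519, and the 1.5-fold rule on both arrays gave 740 and 161. With 1 of the 24 h arrays left out, 1 dye orientation remained at 24 h, so a dye effect did not cancel in the counts of those fits. The replicate block gave 3914 higher and 3683 lower genes. Fitted alone, the 24 h arrays gave 1235 higher and 602 lower genes, so the size of the contrast with the counts at 6 h depended in part on the shared spread. The 1.5-fold rule, which uses no estimate of the spread, gave 212 higher and 13 lower genes at 6 h. By that rule the counts at 24 h stayed larger. The processed signals moved the split to 1242 higher and 1164 lower, and median centring left 13 and 0 in limma (283 and 18 at an unadjusted p under 0.05).

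**Figure D2:**
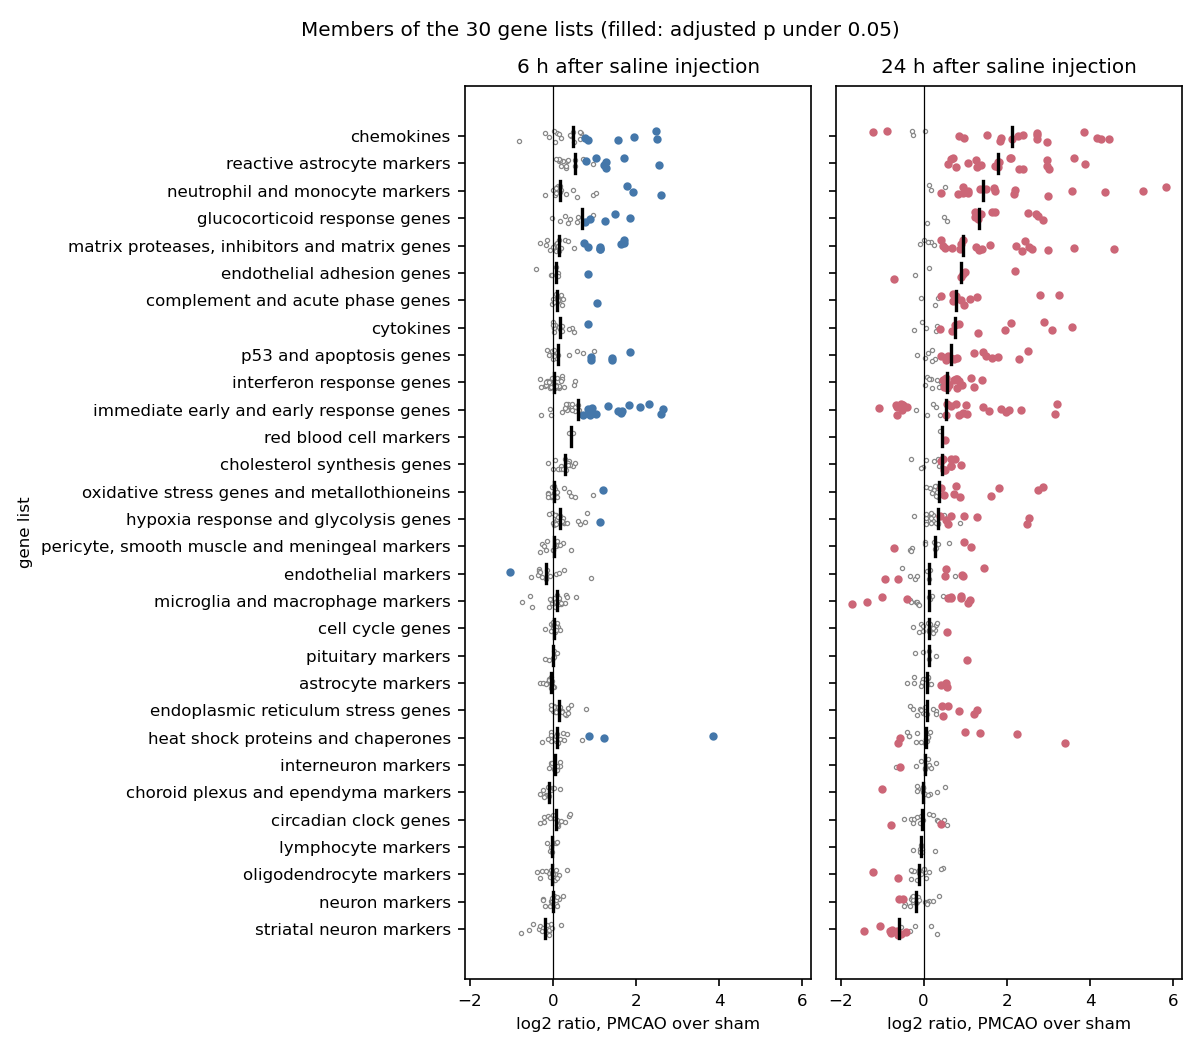
Log2 ratios of PMCAO over sham for the tested members of the 30 gene lists at 6 h (left) and 24 h (right), with the list on the vertical axis, filled points for members past the test, open points for the rest and a bar at the list's median. The chemokine median lay at 0.48 at 6 h and 2.13 at 24 h, and the striatal neuron median at -0.19 and -0.59.

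The PMCAO over sham ratio of some genes differed between the times. That of Mmp3 rose by 4.29 ± 0.19 on the log2 scale from 6 h to 24 h, Chil3 by 3.87 ± 0.18, S100a8 by 3.35 ± 0.14, S100a9 by 3.22 ± 0.14 and Il11 by 3.19 ± 0.13. At 6 h the sham signal of Mmp3 was not well above background on either array and its ratio did not pass (adjusted p = 0.66), so the size of its difference is not measured precisely. Npas4 fell by 2.20 ± 0.28 and Egr4, an early growth response factor, by 1.89 ± 0.13 between the times. Bdnf, a neurotrophin, was higher at 6 h (0.95 ± 0.09) and lower at 24 h (-0.40 ± 0.09), a difference of -1.35 ± 0.12. The test of the difference itself called 248 genes larger and 57 smaller at 24 h.

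The other leading increases were Tgm1, a transglutaminase, at 3.08 ± 0.13, Saa3 at 3.03 ± 0.15, Slpi, a leukocyte protease inhibitor, at 2.85 ± 0.17, Lgals3, a galectin of phagocytes, at 2.71 ± 0.14, and Cxcl1 at 2.69 ± 0.24. At 6 h, sham was not well above background for Saa3 and Tgm1 and neither passed (adjusted p = 0.669 and 0.69), so the same limit holds for their differences. The remaining leading decreases were Khdrbs3, an RNA-binding protein, at -1.42 ± 0.19, Ugt8a at -1.15 ± 0.11 and Fosb at -1.15 ± 0.15. Adjusted p-values of these genes lay between 0.00277 and 0.0359. The 2 probes of Ugt8a spanned -0.07 to -0.02 at 6 h and -1.22 to -0.57 at 24 h, so the size of its decrease depended on the probe. Reactive astrocyte markers had 14 of 21 members with a larger ratio at 24 h and 0 with a smaller one (21 and 0 adjusted over the list alone), neutrophil and monocyte markers 13 of 20 and 0 (18 and 0), chemokines 11 of 21 and 0 (15 and 1), and matrix genes 8 of 25 and 0 (20 and 0). Their camera adjusted p-values were 8.37e-25, 1.03e-22, 2.86e-13 and 1.19e-18 (adjusted p = 0.173 with an estimated correlation for each). Early response genes had 8 of 30 smaller at 24 h and 1 larger (12 and 7 adjusted over the list alone), with a median difference of -0.25 and an adjusted p = 0.00435 (adjusted p = 0.328 with an estimated correlation). The 8 were Bdnf, Dusp6, Egr1, Egr2, Egr3, Egr4, Fosb and Npas4, and the larger one was Ier3. Leaving out 6 h sample 1 or 2 gave 14 or 19 smaller, leaving out 24 h sample 1 gave 1566 larger and 1351 smaller, and leaving out 24 h sample 2 gave 1279 and 768. With an array left out, its time kept 1 dye orientation, so a dye effect did not cancel in these counts. The replicate block gave 1685 larger and 1530 smaller. The processed signals gave 54 and 8, the stricter filter 149 and 30, and median centring 0 and 0 in limma (61 and 4 at an unadjusted p under 0.05).

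Genes that had changed at 6 h mostly kept their direction at 24 h. Of the 163 genes called at 6 h, 157 had the same sign at 24 h and 117 had a larger size there. Atf3, Cd14, Ccl2 and S100a9 were among the 137 genes called higher at both times, where independent lists of these sizes would share 12.2. All 7 lower genes, Erbb3, Gpr17, Slc38a5, Slco1a4, Trim59, Wnt9a and AI593442, were lower at both times, where independent lists would share 0.32. Bdnf, Egr4 and the RIKEN clone C330006P03Rik were called in opposite directions, the last at 1.14 ± 0.08 at 6 h and -1.73 ± 0.08 at 24 h and named after its values were seen. Of the 156 genes called higher at 6 h, 19 were not called higher at 24 h, these 3 included, and another was Npas4 (0.40 ± 0.20, adjusted p = 0.255). Across all genes, which are not independent replicates, the mean log2 ratios of the times correlated at 0.599, and 64.3% of genes had the same sign. The 2 times had separate shams and separate arrays, but their tests shared 1 estimate of each gene's spread. A gene with a small spread was thus favoured in both lists. The lists were therefore not independent, and the numbers for independent lists are no test of the overlap. Where an array was left out, its time kept 1 dye orientation, so a dye effect did not cancel there. The shared higher count was 68 without 6 h sample 2, 596 without 24 h sample 1, 620 without 24 h sample 2 and 501 with each time fitted alone. The shared lower count was 3 or 0 without 6 h sample 1 or 2, and 201 or 105 without 24 h sample 1 or 2.

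The sham signal itself differed between the times. Plin4 was 3.83-fold lower in sham at 24 h than at 6 h (log2 change -1.94 ± 0.07), Sgk1 changed by -1.57 ± 0.09, Depp1, a stress-induced gene, by -1.48 ± 0.12 and Ch25h, cholesterol 25-hydroxylase, by -1.34 ± 0.10. The bicarbonate transporter Slc4a7 changed by -1.98 ± 0.43. Higher at 24 h were Dbpht2 at 1.53 ± 0.09, the DNA methyltransferase Dnmt3a at 1.31 ± 0.10, the oxidase Duox2 at 1.25 ± 0.11 (well above background on 1 of the 2 sham arrays at 6 h), the transcription factor Creb3l3 at 1.24 ± 0.16 and the noncoding RNA Rian at 1.24 ± 0.22. On the same arrays PMCAO changed by 0.18 for Plin4, -0.10 for Sgk1, -0.48 for Depp1, 0.72 for Ch25h and -1.61 for Slc4a7. It changed by 1.13 for Dbpht2, 1.29 for Dnmt3a, 0.82 for Duox2, 0.67 for Creb3l3 and -0.24 for Rian. Where both groups moved alike, as for Dnmt3a and Slc4a7, an array effect cannot be told apart from a change in sham. Of 19117 genes, 497 were higher and 319 lower at 24 h, with adjusted p-values of the named genes between 3.79e-05 for Plin4 and 0.0447 for Slc4a7.

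By list, early response genes had 11 of 30 lower and 3 higher in sham at 24 h, with a median change of -0.16, among them Npas4 at -0.87 ± 0.16 and Fosb at -0.56 ± 0.10. Glucocorticoid response genes had 6 of 14 lower and 0 higher, including Cdkn1a at -0.67 ± 0.07 and Ddit4 at -0.68 ± 0.13. Circadian clock genes had 0 of 16 past the limma test (3 higher at an unadjusted p under 0.05) and a median change of 0.08. Neutrophil and monocyte markers had 1 of 20 lower, S100a8 at -1.15 ± 0.23, and 0 higher. Among the pituitary markers Prl was higher and Cga lower, the latter at -0.91 ± 0.07 with 1 of the 2 sham arrays at 24 h well above background. Cga changed alike in PMCAO, by -0.88. Prl was not well above background in sham at 6 h, so no fold is given. These changes compare channels of different arrays, so an array effect shared by both channels enters them. With an array left out, sham at its time carried 1 dye only, so a dye effect enters as well. Leaving out 6 h sample 1 or 2 gave 35 or 31 higher and 65 or 67 lower, leaving out 24 h sample 1 or 2 gave 1054 or 565 higher and 724 or 409 lower, and median centring gave 0 of either in limma (29 higher and 11 lower at an unadjusted p under 0.05).

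**Figure D3:**
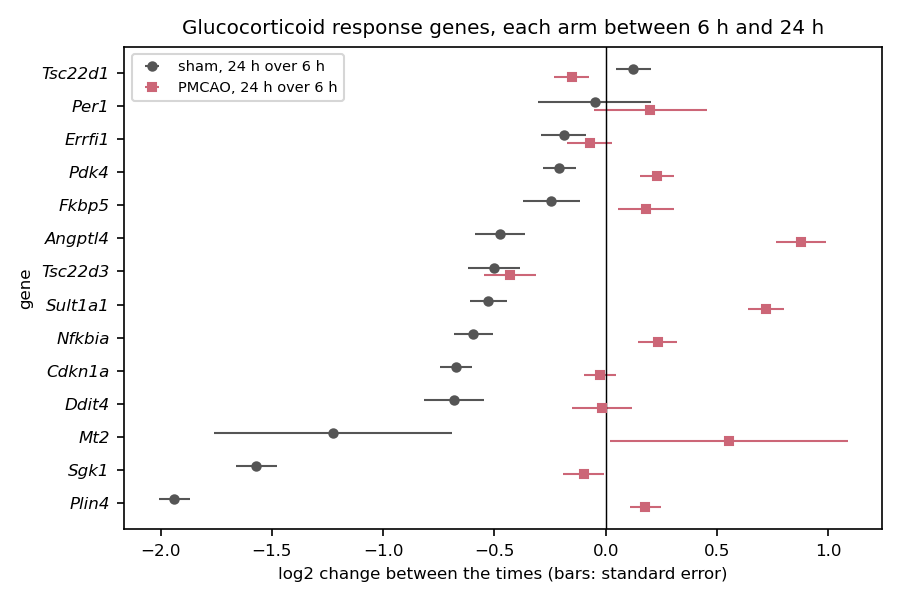
Log2 change from 6 h to 24 h of the 14 tested glucocorticoid response genes within sham (circles) and within PMCAO (squares), with the gene on the vertical axis and standard errors as bars. Plin4 changed by -1.94 in sham, and the list's medians were -0.51 in sham and 0.18 in PMCAO.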

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

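The 24 h minus 6 h difference was planned, while all tests of explanations in this part were chosen after the results were seen. Of the 119 named genes reported here, 44 had a PMCAO over sham ratio that differed between 6 h and 24 h by the test of the difference, 35 with a larger ratio at 24 h and 9 with a smaller one. All values here are 24 h minus 6 h differences on the log2 scale. Among secreted and myeloid genes they were 4.29 for Mmp3, 3.87 for Chil3, 3.35 for S100a8, 3.22 for S100a9, 3.19 for Il11, 3.03 for Saa3, 2.85 for Slpi, 2.71 for Lgals3, 2.69 for Cxcl1, 2.58 for Retnlg and 2.38 for Il1b. Ccl3 stood at 1.90, Lcn2 and Hp at 1.72, Ccl2 at 1.69, Cd14 at 1.33, Cp at 1.03 and Cd68 at 0.96. For Mmp3 and Saa3 sham was not well above background at 6 h, and for 2 further genes, Cxcl3 at 2.64 and Prl at 1.02, neither group was, so these 4 values have no measured 6 h ratio behind them.

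Tgm1, whose sham signal was likewise not well above background at 6 h, differed by 3.08. Plin4 differed by 2.12, Ch25h by 2.06, Timp1 by 1.91, Adm by 1.67, Hmox1 by 1.65, Sgk1 by 1.47, Icam1 by 1.36 and Osgin1 by 1.34. Tubb6 stood at 1.25 on its brighter probe, while its other probe gave 0.05 at 6 h and -0.07 at 24 h. Ifitm3 stood at 1.04, Tmem252 at 1.03, Hspb1 at 1.00, Dcn at 0.97 and Rsad2 at 0.85. Smaller ratios at 24 h were found for Npas4 at -2.20, Egr4 at -1.89, Khdrbs3 at -1.42, Bdnf at -1.35, Fosb and Ugt8a at -1.15, Rxrg at -1.03 and Siglech at -0.92, and the log2 ratio of Slc2a5 fell by 1.00.

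Of the 30 gene lists, 16 shifted between the times in camera with the preset correlation and 0 in limma's camera with an estimated correlation (6 at an unadjusted p under 0.05, smallest adjusted p = 0.173). The median differences were 1.688 for chemokines, 1.282 for neutrophil and monocyte markers, 1.061 for reactive astrocyte markers, 0.759 for endothelial adhesion genes, 0.693 for complement and acute phase genes, 0.671 for cytokines and 0.656 for glucocorticoid response genes. Matrix genes stood at 0.601, interferon response genes at 0.512, endothelial markers at 0.404, oxidative stress genes at 0.386, p53 and apoptosis genes at 0.297 and hypoxia genes at 0.112. Lists with a smaller ratio at 24 h were striatal neuron markers at -0.313, early response genes at -0.249 and neuron markers at -0.154. Fry called 12 of the 16 lists. It did not call these lists with a smaller ratio (fry adjusted p = 0.129, 0.0517 and 0.342) or the hypoxia genes (fry adjusted p = 0.249).

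Neutrophil and monocyte markers were higher at 24 h, with a median log2 ratio of 1.43, and 9 of the 20 were well above background in sham on all arrays. More blood of unchanged makeup in the PMCAO tissue would raise red cell markers alike, and their mean was 0.453 ± 0.062 (SE from the model errors of 2 markers, Hba-a1 at 0.52 and Alas2 at 0.38), which argues against it as the whole cause. Dye bias would reverse between the arrays, and 20 of 20 markers lay above 0 on both 24 h arrays of opposite dye orientation. Blood richer in leukocytes, entry of leukocytes into the tissue and induction in resident cells may each contribute and were not tested.

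Glucocorticoid response genes had a larger ratio at 24 h than at 6 h. The list's median change from 6 h to 24 h was -0.514 in sham and 0.18 in PMCAO, consistent with a fall in sham as part of the difference. Clock genes moved less in sham, with a median size of change of 0.136 over 15 genes. That of 13 glucocorticoid response genes was 0.527 (two-sided permutation test across genes, p = 0.00026). Genes are not independent replicates in that test, and it was chosen after the change in sham was seen, so its p-value overstates the evidence. It cannot decide on different clock hours, since glucocorticoid response genes need not move with the hour by the same size as clock genes. Clock hours therefore stay open as a cause. A response of sham mice to surgery, anaesthesia or injection that fades by 24 h stays open as well, as no untreated mice were measured.

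Striatal neuron markers were lower at 24 h, and dilution by other RNA would lower markers of other resident cells alike, but the median of 14 striatal markers lay 0.523 below theirs (a difference of -0.523, 64 other markers, two-sided permutation test across genes, p = 4e-05). A lower share of neurons of every kind would lower the 22 general neuron markers alike, but striatal markers differed from them by -0.403 (p = 0.00016 by the same permutation test). Both differences argue against these as the whole cause. The striatal list was taken up after its fall was seen, so both p-values overstate the evidence. Less striatum in the dissected PMCAO tissue cannot be told apart from a change within striatal neurons, since the arrays hold no measure of the dissection. That 12 of 14 markers lay below 0 decides neither, as the count restates the pattern. Genes are not independent replicates, and injury to striatal neurons was not tested.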

How the results depend on the processing

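All alternatives were planned, and no test in this part was chosen after the result was seen. No named gene or list that passed the test reversed direction under any alternative in which it was compared. All probes and the 1.5-fold rule gave counts only, so directions of named genes and lists were not compared under them. Tubb6 passed at 24 h on its brighter probe, while its other probe stood at -0.07 and did not pass. Where neither the main fit nor the alternative passed, the sign changed in 84 gene and 44 list comparisons. In all, 4709 gene and 1170 list comparisons were made, those that passed included. Counts given as moved changed by more than 1.5 times, and the cause was not tested except where stated. Where an array was left out, 1 dye orientation remained at its time, so a dye effect did not cancel in the counts that use that time.

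Processed signals gave 22 lower genes at 6 h in place of 7, 54 higher and 8 lower for the difference in place of 248 and 57, and 13 lower at both times in place of 7. The deposited series values, which hold the same ratios, gave 22 lower genes at 6 h, 51 higher and 7 lower for the difference, and 13 lower at both times. Without background subtraction 14 genes were lower at 6 h, 36 lower for the difference and 11 lower at both times. With all probes 4 genes were lower at 6 h and 3 at both times, with trended robust variances 4 at both times, and without a filter 201 were lower in sham in place of 319. The stricter filter gave 149 higher and 30 lower for the difference, and it tested fewer genes.

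Median centring gave 0 higher and 0 lower genes at 6 h, 13 higher and 0 lower at 24 h, 0 of either for the difference, 0 of either at both times and 0 of either in sham. At an unadjusted p under 0.05 limma then gave 62 and 1 at 6 h, 283 and 18 at 24 h, 61 and 4 for the difference, and 29 and 11 in sham. By construction it leaves any dye difference that varies with intensity on the arrays. Of the 185 values of named genes that had passed, 10 still did, and the 191 others of the 376 passed in neither. The 10 were all at 24 h: Ccl2, Ccl3, Ccl4, Cd14, Chil3, Cxcl1, Mmp3, Retnlg, S100a8 and S100a9.

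With the sample number as a replicate block, 1131 genes were higher and 571 lower at 6 h, 3914 and 3683 at 24 h, 1685 and 1530 for the difference, and 825 and 348 at both times. These included each of the 163, 2363 and 305 genes called without it. Samples of the same number share their dye orientation, which the labels give, so the block is also a dye term and needs no pairing. Deviations of same-numbered samples correlated at 0.718 across genes, and the main fit leaves that shared part in its spread. The labels do not say that the numbers pair samples, so dye and pairing cannot be told apart. On simulated arrays the fit with a block recovered 100% of genes changed 1.5-fold, against 8%, 6% and 0% without it, and called 37, 17 and 33 unchanged genes, against 0, at 6 h, at 24 h and for the difference. Those arrays were made with the dye effect and noise of the block fit, so its higher recovery there was fixed in advance.

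Each time fitted alone gave 942 higher and 356 lower at 6 h, 1235 and 602 at 24 h, and 501 and 82 at both times, so that the counts of the times lay closer together. The spread was smaller at 6 h, with a median half-difference between arrays of 0.063 against 0.102 at 24 h. The 1.5-fold rule on both arrays gave 212 higher and 13 lower genes at 6 h, and 740 higher and 161 lower at 24 h. That rule uses no estimate of the spread, and by it the counts at 24 h stayed larger.

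Leaving out each array in turn, with the lone array assumed to vary like the others, gave 76 to 940 higher and 0 to 355 lower genes at 6 h, and 1235 to 2920 higher and 602 to 2841 lower at 24 h. The difference ranged from 167 to 1566 higher and 14 to 1351 lower, and sham from 31 to 1054 higher and 65 to 724 lower. Both times shared 68 to 620 higher and 0 to 201 lower genes. The lowest counts of 0 came without 6 h sample 2, where limma gave 34 lower genes at 6 h at an unadjusted p under 0.05.

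With an estimated correlation all 52 list results that had passed no longer did, and the 38 others of the 90 did not pass either. Processed signals changed the call of 3 of the 90, median centring that of 6, and no background subtraction that of 0. Signal over background limits Mmp3, Saa3 and Tgm1 at 6 h and Cxcl3 at both times, where sham was not well above background.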

Other observations

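The genes in this part were chosen after their values were seen, and no test of an explanation was run on them. Values are log2 ratios of PMCAO over sham ± the standard error of the model of all 4 arrays, with adjusted p-values from limma. Ctla2a and Ctla2b, near-identical inhibitors of cysteine proteases whose probes were not tested for cross-hybridisation, stood at 1.95 ± 0.12 and 1.89 ± 0.10 at 6 h and at 3.81 ± 0.12 and 3.63 ± 0.10 at 24 h.

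Among cytoskeletal genes at 24 h, the alpha tubulin Tuba1c stood at 2.74 ± 0.16 (adjusted p = 0.000723) and the filamin Flnc at 2.59 ± 0.09 (adjusted p = 0.000201). The abundant tubulins Tuba1a at -0.43 ± 0.14 and Tubb2a at -0.41 ± 0.34 did not pass (adjusted p = 0.108 and 0.5).

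At 24 h Procr, a receptor of protein C, stood at 2.70 ± 0.10, Angpt2, an antagonist of the receptor Tie2, at 2.57 ± 0.10, Esm1, a marker of sprouting endothelium, at 2.21 ± 0.11 and Thbd, thrombomodulin, at 1.53 ± 0.09. Itm2a, a membrane protein, was at -1.13 ± 0.10. The lipid droplet gene Plin2 stood at 2.01 ± 0.08 and the fatty acid carrier Fabp4 at 1.67 ± 0.10 (adjusted p = 0.000223 and 0.000722).

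Also at 24 h, the decoy receptor Il1r2 stood at 2.58 ± 0.13, Bcl3 at 2.31 ± 0.11 and Socs3 at 2.29 ± 0.09. Drd4, a dopamine receptor, was higher at both times, at 1.83 ± 0.11 and 1.65 ± 0.11 (adjusted p = 0.00596 and 0.0011). The neuropeptide gene Nts was higher at 6 h at 0.91 ± 0.08 and stood at -0.09 ± 0.08 at 24 h, so that its log2 ratio fell by 1.00 ± 0.11 (adjusted p = 0.024).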
